A study of Mus musculus with 4 samples.

How the data were processed

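RNA sequencing of colonic CD4+ T cells was analysed from 1 deposited table with 4 libraries, 2 for each donor genotype, CK2α fl/fl and CK2α fl/fl with dLck-Cre. Per the labels, total RNA of the sorted cells was extracted with a column kit and libraries were made by a sequencing provider. The reads were placed on the mouse build mm10, per the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation were not given in the sources used here. The deposited values are a signal of gene counts divided by 1 size factor per library, per the name of the deposited table and the values themselves. In every library 100% of the values were whole multiples of 1 step (tolerance 1e-06), the steps equalled the reciprocals of median-of-ratios size factors, and every listed gene had a total of at least 41 reads over the 4 libraries. The recovered reads came to 18517974, 17666457, 16777017 and 22422971 for fl/fl replicates 1 and 2 and dLck-Cre replicates 1 and 2. The design, fixed before the data were examined, had assumed normalized counts, and the table held them.

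Columns were assigned to samples by the names in the labels. Values were tested as log2 of the value plus a pseudocount of 1, so a fold change is on that scale and understates the change of low genes. Genes with a mean of at least 10 were kept, which left 16490 of 16555. The 2 groups were compared with limma 3.58.1 (empirical Bayes with an intensity trend) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Because whole reads could be recovered, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on them as alternatives and called 1133 and 1768 genes. Adjusted p-values that DESeq2 gave as missing were left missing.

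The 31 gene lists were written from general knowledge before the data were examined. They covered CK2 subunits, Th1, Th2, Th17, Treg and Tfh genes, naive and FOXO1 target genes, inhibitory receptors, activation and costimulation, homing, T cell identity, cell cycle, glycolysis, cholesterol synthesis, oxidative phosphorylation, MYC targets, JAK-STAT feedback, NF-kB targets, interferon-stimulated genes, stress, apoptosis, immediate early, mitochondrially encoded and ribosomal protein genes, and markers of CD8 T and NK, gamma-delta T and innate lymphoid, B and plasma, myeloid, granulocyte and mast, epithelial and stromal cells. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. Members were counted over all genes and again adjusted over the list alone.

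The rule for named genes, fixed at the same time, took the CK2 subunits, the 12 largest increases and 12 largest decreases past the threshold with a mean of at least 50 in a group and no overlap between groups, up to 4 members of each list by p-value, and the defining genes of T helper subsets. Names of predicted genes (Gm and digits, LOC), names ending in Rik, pseudogenes and receptor segments were passed over by name and not by annotation, which removed 51 of 1129 candidates, 29 higher and 22 lower. Genes named outside the rule are said to be so, and some genes that the rule takes are not reported here. Coordinates came from GENCODE vM21, which uses the same assembly as mm10, by symbol; 16033 symbols matched 1 gene. Genes with near-identical copies or overlapping partners, such as Reg3b, Mptx1, Gsdmc4, Ifi204, Oas1a, Klri2, ribosomal protein genes and receptor segments, are uncertain because the counting was not stated.

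Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, TMM and quantile normalization, limma without trend or with robust estimation, edgeR, DESeq2, the replicate number as a block, a 2-fold threshold, and leaving out each library. Scaling to 20 T cell identity genes, and edgeR and DESeq2 without each library, were added after the data were seen. The tests were tried on simulated counts for this comparison (16190 genes). There limma recovered 55% of 100 genes changed 2-fold and 94% of 100 changed 4-fold, and 6.29% of its calls were false. The changed genes had a mean of at least 50 and went up as often as down, and genes were drawn independently. In the data most calls were higher and whole lists moved together, so these rates need not apply to them. Exact (Clopper-Pearson) 95% intervals of shares and ratios, from scipy 1.17.1, cover counting error only, since reads without molecular identifiers are not independent molecules. Figures were drawn with matplotlib 3.10.9.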

Results

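RNA was sequenced from CD4+ T cells recovered from the colons of Rag1-/- mice, which lack their own T and B cells, 6 weeks after the animals received CD4+CD25-CD45RBhi T cells, a transfer that causes colitis. The donor cells carried floxed CK2α alleles, and in 1 of the 2 groups also the dLck-Cre transgene, which drives Cre recombinase from the distal Lck promoter in mature T cells. CK2α is the catalytic subunit of the protein kinase CK2, encoded by Csnk2a1. Each group had 2 libraries, and the comparison addresses how loss of CK2α alters CD4+ T cells in the inflamed colon. The deposited table listed 16555 genes, and the whole reads recovered from it came to 18517974 and 17666457 in the fl/fl libraries and to 16777017 and 22422971 in the libraries labelled dLck-Cre. Replicates of a group differed well beyond sampling noise, with a chi-square of 25.4 per gene between the fl/fl libraries and 34.7 between the libraries labelled dLck-Cre. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical in part. T cell receptor segments differed between replicates by a median of 1.59 (log2) in the fl/fl libraries and 1.51 in the libraries labelled dLck-Cre, against 0.225 and 0.253 over all genes, which counts against a purely technical spread.

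The targeted gene was not lower in the libraries labelled dLck-Cre. Csnk2a1 (chromosome 2, 152226839 to 152281852, plus strand, GRCm38) had 1566 ± 44.8 normalized counts in the fl/fl libraries and 2074 ± 61.5 in the libraries labelled dLck-Cre (SD, n = 2 each). Its log2 difference was 0.41 ± 0.13 (SE), which did not pass the test across all genes (limma, adjusted p = 0.108). Csnk2a2, which encodes the other catalytic subunit, differed by -0.09 ± 0.18 (adjusted p = 0.808), and Csnk2b, which encodes the regulatory subunit, by -0.35 ± 0.14 (adjusted p = 0.174). Of the 3 CK2 subunit genes 0 passed over all genes (2 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2) and 1, Csnk2a1, passed as higher when adjusted over the list alone (camera, adjusted p = 0.968). When values were scaled to T cell identity genes, an alternative chosen after the data were seen, Csnk2a1 was 0.90 higher with an adjusted p of 0.00413, and the signs of Csnk2a2 and Csnk2b turned positive. A count per gene cannot show whether an exon was deleted, and the labels do not say which part of the gene is flanked, so every direction below refers to the libraries as labelled.

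Genes past the threshold were mostly higher in the libraries labelled dLck-Cre. Tnfsf4, which encodes the costimulatory ligand OX40L, had 98.6 ± 23.8 normalized counts in the fl/fl libraries and 850.5 ± 370.5 in the libraries labelled dLck-Cre (SD, n = 2 each), a log2 difference of 3.05 ± 0.32 (SE; limma, adjusted p = 0.0195). Il1r1, the interleukin 1 receptor (chromosome 1, 40225080 to 40317257), fell from 1900 ± 3.17 to 431 ± 67.1 normalized counts, a log2 difference of -2.15 ± 0.16 (adjusted p = 0.0195). Of 16490 genes tested, 1150 passed, 948 higher and 202 lower, and 837 of them differed by at least 2-fold, 762 higher and 75 lower. The count depended on the method: limma without the trend called 0 genes (3443 at an unadjusted p under 0.05), limma after quantile normalization 341 (284 higher, 57 lower), edgeR 1133 and DESeq2 1768. Scaling to T cell identity genes, chosen after the data were seen, moved the median of all genes from -0.02 to 0.47 and the share of higher calls from 82.4% to 98.9% (4911 higher and 56 lower of 4967). Without dLck-Cre replicate 2 limma called 0 genes (2810 at an unadjusted p under 0.05), edgeR 71 and DESeq2 416, whereas without any other single library limma called between 1046 and 1231.

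The other genes with the largest increases came from several classes. In the same libraries epithelial and myeloid markers rose, at medians of 1.32 and 1.12. Some of these genes may therefore reflect RNA of other cells, which was not tested gene by gene. They were Mptx1, a mucosal pentraxin (log2 difference 4.59), the collagenase gene Mmp13 (3.56), Fam167b (3.16), the killer cell lectin-like receptor gene Klri2 (3.12), Tgfb2 (2.89) and Nrn1 (2.64). Also among them were the gasdermin gene Gsdmc4 (2.60), the interferon-induced genes Ifi44 (2.56) and Oas2 (2.42), the integrin gene Itgad (2.50) and the immunoglobulin kappa constant gene Igkc (2.46). Mptx1 rested on 1 and 2 reads in the fl/fl libraries against 63 and 68 in the libraries labelled dLck-Cre, a ratio of 37.4 with an exact 95% counting interval of 12.5 to 183.9. Mmp13 had 9 and 1 reads against 34 and 100, a ratio of 11.5 with an interval of 6.06 to 24.5. The largest decreases beside Il1r1, among the gene names that the rule took, were in RP24-233B16.8 (-2.68), which matched no annotated gene, the homeobox gene Vax2 (-2.68), the metalloprotease gene Adam12 (-2.21), and the trefoil factor gene Tff1 (-2.13). The chemokine receptor genes Ccr8 (-2.12) and Ccr4 (-2.09), BC018473 (-2.06), Tmprss3 (-1.84), Qrfp (-1.83) and Acoxl (-1.82) followed. Names ending in Rik were passed over, protein-coding genes included, and some of them had larger decreases than Tmprss3. The interleukin 9 receptor gene Il9r fell from 187 ± 16.9 to 46.5 ± 12.5 normalized counts (SD, n = 2 each). These genes passed limma's test with adjusted p-values between 0.0195 and 0.0499. BC018473 is annotated as antisense, and its reads cannot be separated from those of the opposite strand because the counting is not stated to use strand.

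**Figure D1:**
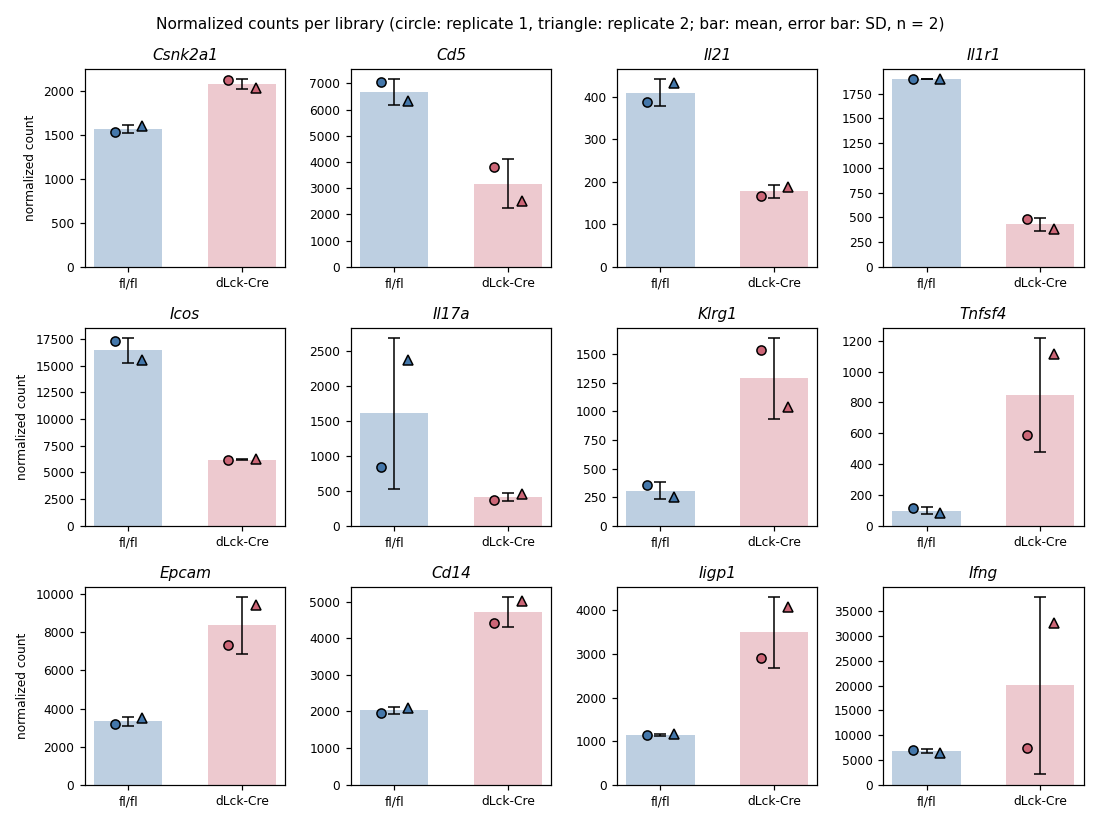
Normalized counts (vertical axes) of 12 genes in the fl/fl libraries and the libraries labelled dLck-Cre. Circles and triangles are replicates 1 and 2, bars are means and error bars SD (n = 2 per group). Il21, Il1r1 and Icos were lower and Epcam and Cd14 higher in both libraries labelled dLck-Cre, while Ifng was high in 1 library only, at 32696 normalized counts.

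Markers of other colonic cells rose in the libraries labelled dLck-Cre, although the cells had been sorted as CD45+CD3+CD4+. Epcam, an epithelial adhesion gene, had 3337 ± 224 normalized counts in the fl/fl libraries and 8383 ± 1497 in the libraries labelled dLck-Cre (SD, n = 2 each; log2 difference 1.32 ± 0.16 SE), and the mucin gene Muc2 differed by 1.27, Reg3b by 1.17 and the claudin gene Cldn7 by 1.35. Of 26 colonic epithelial markers tested, 21 rose over all genes and 25 when adjusted over the list alone, with 0 lower and a median of 1.32 (camera, adjusted p = 5.12e-20; adjusted p = 0.732 with an estimated correlation). Their share of reads was 0.317% ± 0.0179 in the fl/fl libraries and 0.815% ± 0.0945 in the libraries labelled dLck-Cre. Of 32 monocyte, macrophage and dendritic cell markers, 18 rose over all genes and 28 when adjusted over the list alone, with 0 lower and a median of 1.12 (camera, adjusted p = 2.07e-16; adjusted p = 0.732 with an estimated correlation). Il1b (1.31), Cd14 (1.22), Apoe (1.07) and Cd74 (1.25) were among them, and the share of reads was 0.279% ± 0.0981 against 0.651% ± 0.0836.

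T cell identity genes fell in the same libraries. Cd5, a receptor that tunes T cell receptor signals, had 6670 ± 511 and 3161 ± 933 normalized counts (SD, n = 2 each; log2 difference -1.11 ± 0.20 SE), and Cd28 (-0.93) and the adaptor genes Skap1 (-0.68) and Lat (-0.66) also fell. Of 20 T cell identity genes, 6 fell over all genes and 14 when adjusted over the list alone, with 0 higher and a median of -0.51 (camera, adjusted p = 5.44e-10; adjusted p = 0.601 with an estimated correlation). Their share of reads was 0.988% ± 0.00366 in the fl/fl libraries and 0.780% ± 0.0595 in the libraries labelled dLck-Cre. Other lists of cells outside the gate moved less evenly. Of 16 B and plasma cell markers only 5 were tested, of which 2, Igkc (2.46) and Blnk (1.07), rose over all genes. When adjusted over the list alone 4 rose (camera, adjusted p = 0.00231, and adjusted p = 0.732 with an estimated correlation). The list took a mean of 0.00206% of reads in the fl/fl libraries and 0.00532% in the libraries labelled dLck-Cre. Igkc had 14.6 and 32.0 normalized counts against 129 and 120, so this rise rests on few genes and few reads. The Rag1-/- hosts lack their own B cells, so these reads are not shown to come from B or plasma cells. Their source was not tested. Of 14 CD8 T and NK cell markers, 1, the lectin-like receptor gene Klre1 (1.72), rose over all genes and 4 when adjusted over the list alone (camera, adjusted p = 0.0265; adjusted p = 0.732 with an estimated correlation). Klrc1 differed by 0.81 without passing over all genes. Of 23 stromal, endothelial and erythroid markers, 0 passed over all genes (7 at an unadjusted p under 0.05, 0 by edgeR, 2 by DESeq2). When adjusted over the list alone 0 passed, at a median of 0.89 (camera, adjusted p = 0.0241; adjusted p = 0.732 with an estimated correlation). Myh11 was at 1.72 and Pecam1 at -0.60. Of 17 granulocyte and mast cell markers, Csf3r (1.19) alone passed over all genes, as did 1 when adjusted over the list alone (camera, adjusted p = 0.285), and Ly6g differed by 1.11 with overlapping libraries. Of 9 gamma-delta T cell and innate lymphoid markers, 0 passed over all genes (4 at an unadjusted p under 0.05, 0 by edgeR, 2 by DESeq2). When adjusted over the list alone 3 were higher, Sox13 (1.00), Kit (0.95) and Tcrg-C4 (1.19), and 1 lower, Gata3 (camera, adjusted p = 0.506).

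Th17 genes were lower in the libraries labelled dLck-Cre, in which epithelial and myeloid markers were higher and T cell identity genes lower. Il21, a cytokine gene (chromosome 3, 37222759 to 37232636), had 410 ± 32.8 normalized counts in the fl/fl libraries and 178 ± 14.9 in the libraries labelled dLck-Cre (SD, n = 2 each; log2 difference -1.20 ± 0.19 SE; limma, adjusted p = 0.0215). Rora (-0.78), Batf (-0.86), Il1r1 (-2.15) and the cytokine gene Il17a (-1.78) also fell, while Il1rn, which encodes the interleukin 1 receptor antagonist, rose by 1.54. Of 21 Th17 genes, 6 fell and 1 rose over all genes, and 10 fell and 3 rose when adjusted over the list alone, at a median of -0.75 (camera, adjusted p = 2.44e-05; adjusted p = 0.732 with an estimated correlation). Il22 differed by -0.75 ± 0.38 (adjusted p = 0.277). Il17a had 843 and 2374 normalized counts in the fl/fl libraries against 369 and 456, and its difference was -2.53 without fl/fl replicate 1 (adjusted p = 0.000464) and -1.04 without fl/fl replicate 2 (adjusted p = 0.0302). Without dLck-Cre replicate 1 the Il17a difference was -1.63 (adjusted p = 0.0997) and without dLck-Cre replicate 2 it was -1.94 (adjusted p = 0.121), so the call was lost at a similar difference. The Il17a call was also lost with all libraries in under robust estimation (adjusted p = 0.143), quantile normalization (0.0759), a mean of at least 50 (0.0533) and limma without the trend (0.181), and kept with edgeR (0.0385) and DESeq2 (0.0426). After scaling to T cell identity genes, which raised all genes by a similar amount, Il1r1 and Il21 still passed as lower, and Rora, Batf and Il17a did not.

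Th1 genes did not move together. Epithelial and myeloid markers were higher in the same libraries, so members of the lists below that rose need not have risen in T cells. This was not tested. Tbx21, which encodes the Th1 factor T-bet, differed by 0.06 ± 0.27 (SE; limma, adjusted p = 0.925). Ifng had 7025 and 6435 normalized counts in the fl/fl libraries and 7454 and 32696 in the libraries labelled dLck-Cre, so that 1 library set its difference of 1.22 ± 0.57 (adjusted p = 0.244). Without dLck-Cre replicate 2 the difference was 0.15, and without replicate 1 it was 2.28 (adjusted p = 0.0054). Of 23 Th1 genes, 0 passed over all genes (6 at an unadjusted p under 0.05, 0 by edgeR, 3 by DESeq2). When adjusted over the list alone 2 were higher, Gzmk (0.74) and Eomes (0.71), and 1 lower, Il18r1 (-0.66) (camera, adjusted p = 0.937), with a median of -0.13 and a mean of 0.03. Of 11 Th2 genes, Ccr4 (-2.09) and Ccr8 (-2.12) fell and Pparg (1.56) rose over all genes, and 3 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.56). Gata3, the Th2 factor, differed by -0.72 ± 0.19 (adjusted p = 0.0729). Of 17 Treg genes, 3 rose and 3 fell both over all genes and when adjusted over the list alone (camera, adjusted p = 0.937). Klrg1 (2.07) and the ectonucleotidase gene Entpd1 (0.96) rose and Icos (-1.41) and Ctla4 (-1.04) fell. Ikzf2 (1.21) rose and Tigit (-1.09) fell as well, and these 2 were named after their values were seen. Foxp3, the Treg factor, was listed at 16.6 and 13.3 normalized counts in the fl/fl libraries and at 4.18 and 31.1 in the libraries labelled dLck-Cre (adjusted p = 0.868), and the sign of its difference turned with edgeR and DESeq2. Of 10 Tfh genes, Btla (-0.97), Il21 (-1.20), Tox2 (-1.24) and Izumo1r (-1.34, named after its value was seen) fell and Cxcr5 (1.36) rose over all genes, and 4 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.0457; adjusted p = 0.732 with an estimated correlation). The Tfh median of -0.40 became 0.09 after scaling to T cell identity genes. Btla (-0.48) and Il21 (-0.71) then still passed limma's test as lower and Cxcr5 (1.85) as higher, and Tox2 no longer passed.

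Part of the T cell activation and costimulation genes fell in the libraries labelled dLck-Cre, beside the lower T cell identity genes and the higher epithelial and myeloid markers. Icos (chromosome 1, 60977927 to 61000320) had 16443 ± 1205 normalized counts in the fl/fl libraries and 6196 ± 48.8 in the libraries labelled dLck-Cre (SD, n = 2 each; log2 difference -1.41 ± 0.13 SE; limma, adjusted p = 0.0195), and the CD40 ligand gene Cd40lg (-1.27), Cd5 (-1.11) and Cd28 (-0.93) also fell. Of 25 T cell activation and costimulation genes, 7 fell and 1, Spry2 (1.31, named after its value was seen), rose over all genes, and 8 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.0262; adjusted p = 0.732 with an estimated correlation). Of the 25, 10 lay above 0. The list's median of -0.23 became 0.27 after scaling to T cell identity genes. Then 5 members passed limma's test as higher and 2 as lower, Icos (-0.91, adjusted p = 0.00485) and Cd40lg (-0.77, adjusted p = 0.0159). Cd5 (adjusted p = 0.0548) and Cd28 (adjusted p = 0.0928) no longer passed. Of 15 inhibitory receptor and exhaustion genes, Ctla4, Btla, Cd160 (-1.24) and Tigit fell and Entpd1 rose over all genes, and 4 fell and 2 rose when adjusted over the list alone (camera, adjusted p = 0.0824). Of 24 homing and trafficking genes, the sphingosine 1-phosphate receptor gene S1pr4 (-1.01), Itgae, which encodes the CD103 integrin chain (-1.55), the chemokine receptor genes Cxcr6 (-0.77) and Cxcr4 (-0.62) fell over all genes, and 3 genes rose, Ccr7 (0.84) and Gpr15 (1.26) among them. In all, 7 fell and 3 rose when adjusted over the list alone (camera, adjusted p = 0.0804). Cxcr4 and Gpr15 were named after their values were seen. Of 21 naive T cell and FOXO1 target genes, 3 rose over all genes, Ccr7 and Ddr1 (0.92) among them, and Il7r (-0.71) fell, and 7 rose and 7 fell when adjusted over the list alone (camera, adjusted p = 0.738). Foxo1 itself differed by -0.64 ± 0.19 (adjusted p = 0.0913).

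**Figure D2:**
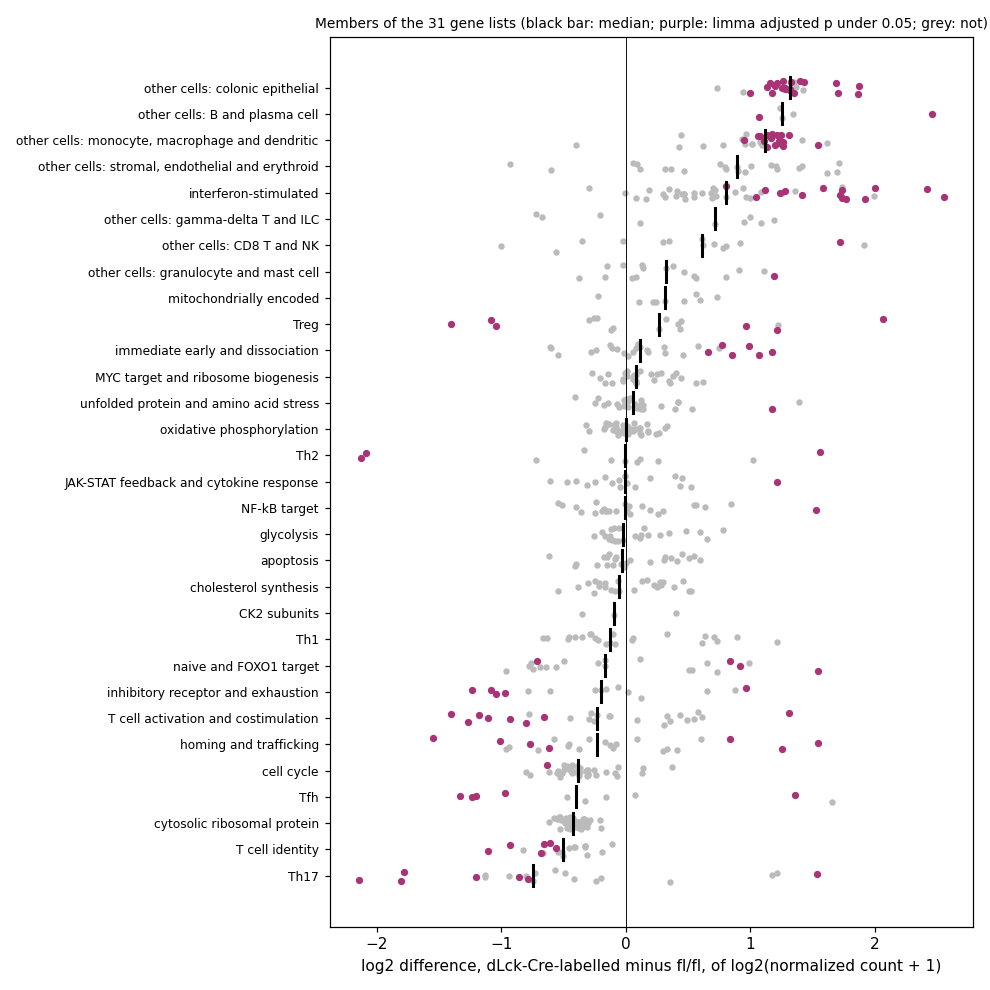
Log2 differences (horizontal axis, libraries labelled dLck-Cre minus fl/fl, of log2 of the normalized count plus 1) of the tested members of 31 gene lists; black bars are medians, purple points passed limma's test over all genes and grey points did not. The medians of the epithelial, the B and plasma cell (only 5 of 16 members tested) and the myeloid markers lie highest and those of Th17 and T cell identity genes lowest.

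Interferon-stimulated genes rose in the libraries labelled dLck-Cre, in which epithelial and myeloid markers rose as well. Iigp1, an interferon-inducible GTPase gene, had 1149 ± 20.8 normalized counts in the fl/fl libraries and 3500 ± 819 in the libraries labelled dLck-Cre (SD, n = 2 each; log2 difference 1.59 ± 0.18 SE; limma, adjusted p = 0.0195), and Ifi204 (1.92), Irgm1 (1.24) and Oas1a (1.74) also rose. Interferon-stimulated genes took 0.238% and 0.229% of reads in the fl/fl libraries and 0.335% and 0.472% in the libraries labelled dLck-Cre, so both were higher and replicate 2, the library with the high Ifng, more so. Oas1a had 488 and 963 normalized counts in these libraries against 196 and 213, and Ifi44 had 73.2 and 247 against 31.2 and 15.5. Of 47 interferon-stimulated genes, 15 rose over all genes and 36 when adjusted over the list alone, with 0 lower and a median of 0.81 (camera, adjusted p = 3.45e-15; adjusted p = 0.732 with an estimated correlation). Of 27 immediate early and dissociation genes, 6 rose over all genes and 8 when adjusted over the list alone (camera, adjusted p = 0.0262; adjusted p = 0.732 with an estimated correlation), with Atf3 (1.17), Ier3 (0.99), Zfp36 (0.85) and Rhob (0.66) among them. Of 28 unfolded protein and amino acid stress genes, Atf3 alone rose over all genes and 1 rose when adjusted over the list alone (camera, adjusted p = 0.56), and Chac1 differed by 1.40 without passing. Of 19 JAK-STAT feedback and cytokine response genes, the cytokine gene Osm (1.22) rose over all genes, and 1 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 0.963). Jak3 differed by -0.61. Of 25 NF-kB target genes, Cd83 (1.53) rose over all genes and 1 rose when adjusted over the list alone (camera, adjusted p = 0.963), and Birc2 differed by -0.51.

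Cytosolic ribosomal protein genes lay below 0 as a group. Rpsa had 57110 ± 287 normalized counts in the fl/fl libraries and 37405 ± 4953 in the libraries labelled dLck-Cre (SD, n = 2 each; log2 difference -0.62 ± 0.16 SE), and Rpl17 differed by -0.58. Of 52 such genes, 0 passed over all genes (44 at an unadjusted p under 0.05, 0 by edgeR, 9 by DESeq2). When adjusted over the list alone 42 were lower, at a median of -0.43 that became 0.07 after scaling to T cell identity genes (camera, adjusted p = 2.07e-16; adjusted p = 0.732 with an estimated correlation). Reads of these genes can be split with processed pseudogenes, so single values are uncertain. Of 41 cell cycle genes, the replication licensing gene Mcm6 (-0.63) alone fell over all genes and 0 passed when adjusted over the list alone, at a median of -0.38 that became 0.11 after the same scaling (camera, adjusted p = 4.46e-07; adjusted p = 0.732 with an estimated correlation). Mki67, a proliferation marker, differed by -0.37 ± 0.14 (limma, adjusted p = 0.168), and Hist1h3c by -0.77.

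Metabolic and survival genes did not pass limma's main test over all genes in any of 6 lists, though some passed with DESeq2 or after scaling to T cell identity genes. In each of them 0 genes passed limma's test over all genes and 0 when adjusted over the list alone, and edgeR called 0. At an unadjusted p under 0.05 were 3 glycolysis, 5 cholesterol synthesis, 1 oxidative phosphorylation, 2 MYC target, 6 apoptosis and 0 mitochondrially encoded genes. DESeq2 called 1 cholesterol synthesis gene and 1 MYC target and 0 in the other 4 lists. After scaling to T cell identity genes, which moved the median of all genes from -0.02 to 0.47, 12 of 23 glycolysis, 11 of 25 cholesterol synthesis, 21 of 38 oxidative phosphorylation, 23 of 30 MYC target, 11 of 24 apoptosis and 2 of 9 mitochondrially encoded genes passed as higher. So did 6 Th1 genes, 5 stromal, endothelial and erythroid markers and 3 gamma-delta T cell and innate lymphoid markers, of which 0 had passed over all genes before. The camera test gave adjusted p = 0.919 for 23 glycolysis genes, 0.994 for 25 cholesterol synthesis genes, 0.994 for 38 oxidative phosphorylation genes, 0.285 for 30 MYC target and ribosome biogenesis genes, 0.968 for 24 apoptosis genes and 0.285 for 9 mitochondrially encoded genes. Pfkfb4 (0.78) and Slc2a1 (0.49) of glycolysis, Cyp51 (-0.54) of cholesterol synthesis, Cyc1 (0.33) of oxidative phosphorylation and Nop2 (0.62) of the MYC targets were among the members with the smallest p-values of their lists. The mitochondrial gene mt-Nd6 differed by 0.60 ± 0.35 with overlapping libraries. Of the 31 lists, 13 passed the camera test with its preset correlation, 7 higher and 6 lower, and 0 did with an estimated correlation or by fry. The preset correlation was assumed, and with 2 libraries per group an estimated one rests on little data. Even the epithelial list, with all 26 members above 0, had an unadjusted p of 0.071 by camera with it. The 0 therefore does not show that the lists did not move.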

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

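The scaling to T cell identity genes and the edgeR and DESeq2 fits without each library were chosen after the data were seen. The use of edgeR and DESeq2 with all libraries depended on the recovery of whole reads from the deposited values. The other alternatives were fixed before the data were examined. The cause was not tested where a result changed, unless stated. The number of genes past the threshold stayed within 1.5 times of 1150 under both pseudocounts, both filters, TMM, robust estimation and edgeR. It was 341 (284 higher, 57 lower) under quantile normalization, 1768 with DESeq2 (421 lower), and 4967 (4911 higher, 56 lower) after scaling to T cell identity genes. Without the trend limma called 0 genes, 0 higher and 0 lower, with 3443 at an unadjusted p under 0.05 and 1133 called by edgeR. At least 2-fold differences left 75 lower genes, as fewer can pass. Csnk2a1 was 0.90 higher after scaling to T cell identity genes. Past the threshold were 13 lists, 0 with an estimated correlation and 0 by fry (camera on edgeR values called 13).

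With the replicate number as a block 2096 genes passed (1476 higher, 620 lower), including all 1150. Replicate differences correlated across genes at 0.110, genes are not independent replicates, and there were only 2 pairs. The labels do not say that a number marks a shared animal or day, so the numbers were not taken to pair the libraries, and a shared batch stays open.

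Leaving out a library gave between 0 and 1316 genes, between 0 and 1055 higher and between 0 and 296 lower; the lone library of a group is then assumed to vary like the others. The 0 came from limma without dLck-Cre replicate 2 (2810 at an unadjusted p under 0.05, 71 by edgeR, 416 by DESeq2). Without fl/fl replicates 1 and 2 DESeq2 called 688 and 749. Differences ranged from -0.00039 to 1.19 for mt-Nd6, -0.30 to 0.12 for Csnk2a2, -0.38 to 0.50 for Tbx21 and -1.61 to 1.02 for Foxp3. Adjusted p-values of lists that changed sign ranged from 0.539 to 0.939 for glycolysis, 0.163 to 0.503 for oxidative phosphorylation, 0.0508 to 0.941 for NF-kB targets, 0.00181 to 0.858 for mitochondrially encoded genes, 0.00223 to 0.589 for granulocyte and mast cell markers, 0.774 to 0.969 for CK2 subunits, 0.3 to 0.606 for Th1, 0.139 to 0.793 for cholesterol synthesis, 0.00974 to 0.606 for JAK-STAT feedback, 0.623 to 0.939 for apoptosis, 0.168 to 0.86 for Treg and 0.0671 to 0.793 for gamma-delta T and innate lymphoid markers.

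Some signs changed with all libraries in. Scaling to T cell identity genes turned Csnk2a2 (0.40), Csnk2b (0.14), Foxp3 (0.16) and Mki67 (0.13) positive, and edgeR (0.30) and DESeq2 (0.26, no adjusted p) turned Foxp3. Lists that changed sign had these adjusted p-values. After T cell scaling they were 0.575 for CK2 subunits, 0.463 for Treg, 0.00211 for oxidative phosphorylation, 0.803 for JAK-STAT and 0.572 for NF-kB. Under quantile normalization they were 0.798 for CK2 subunits, 0.518 for Th1, 0.0412 for oxidative phosphorylation, 0.38 for JAK-STAT and 0.0979 for NF-kB. At a mean of at least 50 they were 0.906 for oxidative phosphorylation and 0.999 for JAK-STAT and NF-kB, and with TMM 0.937 for oxidative phosphorylation. Cholesterol synthesis had 1 at a pseudocount of 5, 0.998 with no filter, 0.96 with edgeR and 0.995 with the block, and apoptosis 0.991 with edgeR. By fry CK2 subunits, oxidative phosphorylation and JAK-STAT had 0.957. Of the other values of named genes with all libraries, 1161 kept their direction and side of the threshold, 157 lost and 53 gained the call. At these depths and with 2 libraries per group, limma recovered 55% of simulated 2-fold changes. That simulation had as many rises as falls, which the data did not have.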

Other observations

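Of the tests below, the one on second marker lists was written before its result was seen and the others after.

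A small stretch of chromosome 17 held neighbouring genes that were lower together, chosen after their values were seen. Tff1 (31161395 to 31165277, GRCm38) had 1544 and 1386 normalized counts in the fl/fl libraries and 407 and 274 in the libraries labelled dLck-Cre, and Tmprss3 (31179265 to 31198977) had 70.7 and 84.0 against 23.0 and 18.8. Gm15318, which overlaps Tff1 on the other strand, had 35.3 and 32.0 against 8.36 and 8.19, and its reads cannot be separated from those of Tff1 without strand. The T cell gene Ubash3a beyond Tmprss3 was lower by -0.68 (limma, adjusted p = 0.0283). Further out on either side, Tff3, a goblet cell gene, was higher by 1.40 (limma, adjusted p = 0.0197) and Slc37a1 by 0.63 (adjusted p = 0.0396). These genes were picked by name, so other genes may lie between them. Tff1 moved against Tff3 and against all 26 epithelial markers tested.

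T cell receptor segments differed widely between replicates of a group. Over 56 segments tested the median absolute difference between replicates was 1.59 (log2) for fl/fl and 1.51 for the libraries labelled dLck-Cre, against 0.225 and 0.253 over all genes. Trbv13-2 took 14.3% (exact 95% interval 13.5 to 15.0) and 29.0% (28.0 to 30.1) of Trbv reads in the fl/fl libraries and 14.3% (13.4 to 15.3) and 39.3% (38.3 to 40.4) in the libraries labelled dLck-Cre. Trbv20 took 8.15% (7.56 to 8.76) and 0.121% (0.0555 to 0.230) against 0.330% (0.199 to 0.514) and 5.76% (5.27 to 6.28). Of the 56 segments 4 passed limma's test, all lower, a share similar to the 1150 of 16490 over all genes. The test draws each error toward that of all genes, whose replicates differed less, so these calls are uncertain. The 4 segments were Trbv30, Trbv4, Trav7-1 and Trav14-3, the last listed at 0 in both libraries labelled dLck-Cre. Gm26917 took 2.32% and 2.57% of reads in the first replicates and 3.54% and 4.63% in the second (fl/fl, then dLck-Cre), so it was higher in the second replicates and, within each number, in the library labelled dLck-Cre. Gm42418 followed the replicate number, at 0.205% and 0.195% against 0.407% and 0.403%.

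Epithelial and myeloid markers were higher and T cell identity genes lower in the libraries labelled dLck-Cre. A difference in depth is argued against, since the shallowest of these libraries lay 1.09 (log2) above the higher fl/fl library in mean epithelial marker level. A lower share of T cell RNA with an unchanged mix of other cells was not decided. Epithelial markers lay 0.969 above granulocyte and mast cell markers in mean log2 difference (permutation p over genes = 1e-05, the smallest possible). The lists were compared because their rises had been seen to differ, and genes of a list are not independent. This p-value therefore cannot weigh against that explanation. Per library the gap between these lists was 2.82 and 2.28 for fl/fl and 3.46 and 3.58 for dLck-Cre, and its difference stayed between 0.701 and 1.24 without any 1 library. The granulocyte list was taken after its small rise was seen, and its camera call changed with the fl/fl library left out (adjusted p = 0.589 without fl/fl replicate 1 and 0.00223 without fl/fl replicate 2). Epithelial markers also rose more than stromal (0.564), CD8 T and NK (0.838) and gamma-delta T and innate lymphoid markers (0.94). The libraries of the 2 groups did not overlap in these gaps. Myeloid and B and plasma cell markers did not separate from epithelial markers, at 0.278 and -0.152 with overlapping libraries. The hosts lack their own B cells, so what the latter list measures is unclear. The lists thus moved unevenly, but these comparisons too came after the data were seen. Whether all other cells rose evenly therefore stays open. In second lists the median was 1.147 for 25 epithelial genes, of which 24 were above 0, and 1.05 for 24 myeloid genes, of which 23 were. It was -0.53 for 19 T cell genes, all below 0. These are further markers of the same cells in the same libraries, so they repeat the pattern and do not test its source. More RNA of other colonic cells may account for the pattern, although the sort for CD45+CD3+CD4+ should remove such cells. Whether such RNA follows from the donor genotype, the severity of colitis or the sort was not tested, and with 2 libraries per group these stay open.

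Th17 genes were lower in the same libraries, which dilution of T cell RNA could also produce. The Th17 median lay -0.242 from that of T cell identity genes (permutation p = 0.082), and 4 of the 21 members were above 0, so dilution and a fall within T cells cannot be told apart for the list. Whether the members above 0 rose in T cells or came with RNA of other cells was not tested. Of the 6 members that had fallen, 3 still passed after scaling to T cell identity genes, among them Il1r1 (-2.15 ± 0.16 before and -1.65 ± 0.16 after, SE) and Il21 (-1.20 ± 0.19 and -0.71 ± 0.19). Rora (-0.78 ± 0.15 and -0.29 ± 0.16), Batf (-0.86 ± 0.15 and -0.36 ± 0.16) and Il17a (-1.78 ± 0.42 and -1.29 ± 0.41, adjusted p = 0.0513 after) did not. The scaling raised all 6 by nearly the same amount, so which of them still passed followed from their differences and errors before it, and says only that some fell further than T cell identity genes. The members were picked because they had fallen and the scaling rests on 20 genes, so a lower Th17 program in cells of the labelled genotype remains a hypothesis.

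Csnk2a1 was not lower in the libraries labelled dLck-Cre. Exchanged group labels could show as a lower Csnk2a1 in the libraries labelled fl/fl. Both of these (1534 and 1597 normalized counts) did lie below both libraries labelled dLck-Cre (2118 and 2031). The difference of 0.406 (limma, adjusted p = 0.108) lay at the percentile 75.6 of all genes. It fell short of a log2 difference of 1 past the threshold, taken as the sign of an exchange. That bar was set after the value was seen, so missing it counts neither for nor against an exchange. The 0.90 after scaling to T cell identity genes adds nothing to this, since the scaling raises all genes by a similar amount. The gene was not lower in the libraries labelled dLck-Cre either, which would have counted against an exchange. An exchange cannot be told apart from a deletion that leaves the transcript countable, since gene counts do not show the flanked exons. If T cells labelled dLck-Cre made no Csnk2a1 transcript and other cells rose as epithelial markers did, other cells would have had to make 53.1% of the Csnk2a1 reads of the fl/fl libraries. Epithelial markers had the highest median among the lists of other cells, so this share is a low estimate. Stromal markers, at a median of 0.89, and granulocyte and mast cell markers, at 0.32, rose less, and a smaller rise would need a larger share. A partial loss would need less, and the level of the gene in other cells was not measured. Escape of T cells from deletion was not tested, and reads over the flanked exons would be needed to decide.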
